A study of Mus musculus with 6 samples.

How the data were processed

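RNA was measured in 6 libraries of mouse calvaria-derived cells, 3 from wt (C57BL/6) mice and 3 from mice homozygous for the gld mutation of Fasl, which the labels call FasL KO and which are called gld here. Per the labels' protocols, total RNA went into QuantSeq 3′ mRNA-Seq FWD libraries, whose reads start inside the transcript near its 3′ end and run towards the poly(A) tail, and which so give about 1 tag per molecule whatever its length. Reads were single-end, 75 nt. Per the series' design text, the sequencing company trimmed reads with Cutadapt, aligned them with STAR and checked quality with FastQC, RSeQC and MultiQC. The submitters' processing notes name FastQC, Trim Galore, DESeq2 and the mm10 build without versions. The counter, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes cannot be assigned with certainty, and genes with near-identical copies are uncertain.

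The deposited table holds whole-number read counts per Ensembl gene, not normalized, and these counts were analysed as deposited. It has 57180 rows with an identifier and 1 empty row without an identifier or any count, which was left out. Another 1 identifier is not of full length and has no symbol. Symbols were found for 51883 identifiers and GRCm38 positions for 51932, from GENCODE mouse release M21 and a table of gene names. No fold changes or p-values were in the table, and 0 columns of samples were left unused.

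The counts depend on how many annotated transcripts share the end of a gene. The last 300 exonic bases of each gene's principal transcript were laid over all its transcripts in GENCODE M21, and an end counts as single where at least 99% of these bases lie in 1 transcript. Genes were split this way after low counts of everyday genes had been seen. Among proteasome and respiratory chain genes, 46 with an end in a single transcript had a median of 770 counts summed over the 6 libraries, and 47 with a shared end had a median of 0. Their difference in mean log10(count + 1) had p = 2e-05 in a two-sided permutation test with 100000 resamples, the smallest p these can give. Of all protein-coding genes, 51.6% of 11206 with a single-transcript end and 81.2% of 7754 with a shared end had under 30 counts. A count of 0 therefore means here that a gene is listed at 0, not that it has no transcript. Of the 650 different genes in the fixed lists, 368 could be tested, and 149 of the 282 others were at 0 in every library. Of the 8692 genes tested, 6963 have a single-transcript end.

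Genes were kept by filterByExpr, which asks for about 10 counts in the smaller group's number of libraries and 15 in total, and libraries were scaled by TMM. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of gld against wt over all 6 libraries with no covariate and Benjamini-Hochberg adjustment, called at an adjusted p of 0.05. Fold changes are log2, gld minus wt. Standard errors were derived as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM on the TMM scale, mean ± SD over 3 libraries. Where a group had no count, the fold is the other group's mean divided by a floor of 3 counts over the group without counts. It is called a lower bound here, but it leaves out the error of the other group's mean. Where a group had 1 to 3 counts, the ratio of pooled counts is given with its 95% exact counting interval. The labels mention no unique molecular identifiers, so intervals and floors cover counting error only.

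The 31 gene lists, the rule for named genes, the tests and most of the other settings tried were fixed before the data were examined. Named genes are Fasl and Fas, then the 10 largest increases and 10 largest decreases by fitted fold change among called genes with non-overlapping groups and a mean normalized count of at least 50, passing over unnamed gene models and pseudogenes. From each list up to 4 called members are named in order of adjusted p, or up to 2 as values where none was called, and 1 gene that this rule names is not reported here. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, two-sided, adjusted over the 31 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction without comparing them with other genes, were run beside it. The share of called genes within 20 Mb of Fasl was compared with that of all other genes by Fisher's exact test, two-sided.

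Both tests were run on simulated data with the real genes' means, dispersions and library sizes over 8692 genes. Each gene was drawn independently, so the simulated lists hold no correlation between genes. For gld versus wt, changes were planted in 200 genes in sets of 50 per fold size. At 1.5-fold 6% were recovered, at 2-fold 36%, at 4-fold 60% and at 8-fold 74%, with 4 unplanted genes among 92 calls. Fewer genes were changed than the 1515 called in the real data, which makes the Benjamini-Hochberg adjustment stricter. These shares therefore do not measure recovery in the real data. A shift of 0.7 log2 units planted in the collagen list had a camera adjusted p = 1.79e-12, and an adjusted p = 0.111 with an estimated correlation, and 0 of 28 unchanged lists were called by camera. Among the lists that camera called in the real data, estimated correlations ran from −0.148 to 0.382. How often camera calls unchanged lists of correlated genes is therefore not shown by the simulation.

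Totals ran from 2011173 to 5245546 counts per library, and each gld library was deeper than each wt library. Library pairs within a group differed by more than sampling noise, with chi-square per degree of freedom from 6.44 to 15.0, so no library was treated as a duplicate. Alternatives covered DESeq2 size factors, library size alone, DESeq2 (1.42.0), limma-voom, other filters and thresholds, each library left out, the replicate number as a block, and other windows around Fasl. After the data were seen, libraries thinned to the smallest total, a fit without mitochondrial genes and pseudogenes, and a fit on genes with a single-transcript end were added. Cells treated with soluble Fas ligand, an arm in the design text, were not analysed here.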

Results

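Calvaria-derived cells, which grow out of the bone of the skull vault, were cultured in osteogenic medium with ascorbate and β-glycerophosphate and profiled by 3′ end sequencing of their mRNA. The 3 wt libraries came from cells of C57BL/6 mice. The 3 gld libraries came from cells of mice homozygous for gld, a point mutation in Fasl, which encodes Fas ligand, the ligand of the death receptor Fas. The stated aim was to identify components of the extracellular matrix that a lack of functional Fas ligand affects in osteoblasts. Nothing in the labels says whether the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical.

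The wt libraries held 2011173, 3105322 and 3054280 counts and the gld libraries 4210024, 4048258 and 5245546. The 20 most abundant genes took 18.5% ± 0.92 (SD, n = 3) of the counts in wt and 27.6% ± 0.64 (SD, n = 3) in gld, without overlap. A two-sided exact permutation test of 3 against 3 libraries cannot go below p = 0.1. On the first principal component of the 500 most variable genes, which carried 82.4% of their variance, the wt libraries lay between −45.4 and −41.7 and the gld libraries between 41.3 and 47.6. Gapdh, Tpt1, Ftl1, Timp1 and Serpinh1, genes of general cell functions and of the matrix that were picked after their counts were seen, were listed at 0 in all 6 libraries, while B2m held 136947 counts and Lum 49582 in sum. Among ribosomal protein genes, the 19 whose last 300 exonic bases lie in a single annotated transcript had a median of 442 counts over the 6 libraries, and the 39 whose end is shared between transcripts had a median of 3.

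**Figure D1:**
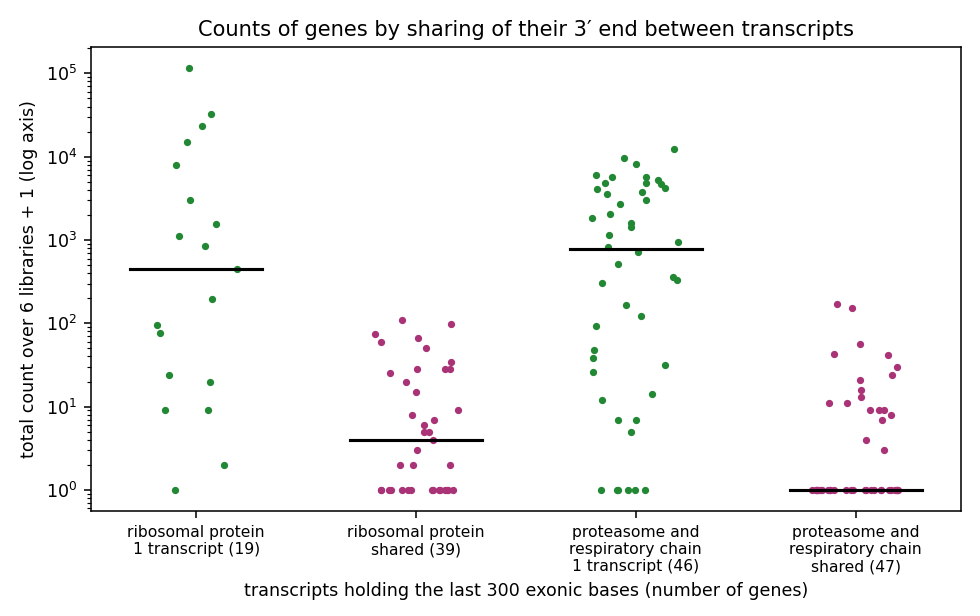
Total count over the 6 libraries plus 1, on a log axis, of ribosomal protein genes and of proteasome and respiratory chain genes (1 point per gene, bar at the median), split by whether their last 300 exonic bases lie in a single annotated transcript. Medians are 442 against 3 counts for ribosomal protein genes and 770 against 0 for proteasome and respiratory chain genes.

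Fasl (ENSMUSG00000000817, GRCm38 chromosome 1, 161780689 to 161788495, minus strand) was listed at 0 counts in all 6 libraries. By counting error alone a count of 0 allows up to 0.367 CPM over the wt group and 0.222 CPM over the gld group. Unlike Gapdh, which has a shared end, Fasl has 100% of its last 300 bases in a single transcript. Because Csf1r, which also has a single-transcript end, is listed at 0 as Gapdh is, the count of 0 sets no firm bound on the transcript itself. Because gld is a point mutation and no read of the gene was counted, the transcript level checks neither genotype label. Fas, the receptor, had 78, 111 and 68 counts in wt and 134, 100 and 150 in gld, or 30.9 ± 8.69 CPM against 30.2 ± 3.57 CPM (SD, n = 3). Its log2 fold change was −0.03 ± 0.31 (SE), with an edgeR adjusted p = 0.973, and the last 300 bases of Fas are shared by several of its 5 annotated transcripts.

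The comparison of gld with wt asks which transcripts differ in osteogenic cultures without functional Fas ligand. Osteoglycin (Ogn), a small leucine-rich proteoglycan of bone, went from 6.23 ± 3.83 CPM in wt to 2506 ± 217 CPM in gld, and collagen I transcripts (Col1a1) from 7621 ± 1653 to 27140 ± 1821 CPM (SD, n = 3). In the other direction, Ptgs2, which encodes the inducible cyclooxygenase of prostaglandin synthesis, fell from 3501 ± 510 to 85.2 ± 3.69 CPM, and Grem1, which encodes a BMP antagonist, fell from 6226 ± 783 to 543 ± 23.3 CPM. Of 8692 genes tested, 1515 (17.4%) were past an adjusted p of 0.05 in edgeR's quasi-likelihood test, 847 higher and 668 lower in gld. A change of at least 2-fold was seen in 606 of the higher and 416 of the lower genes. Groups did not overlap in 1506 of the called genes and in 33.3% of tested genes, where chance gives 10%. Scaled by library size alone, which moved the median log2 fold change of all genes from 0.02 to −0.14, edgeR called 720 genes higher and 975 lower.

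**Figure D2:**
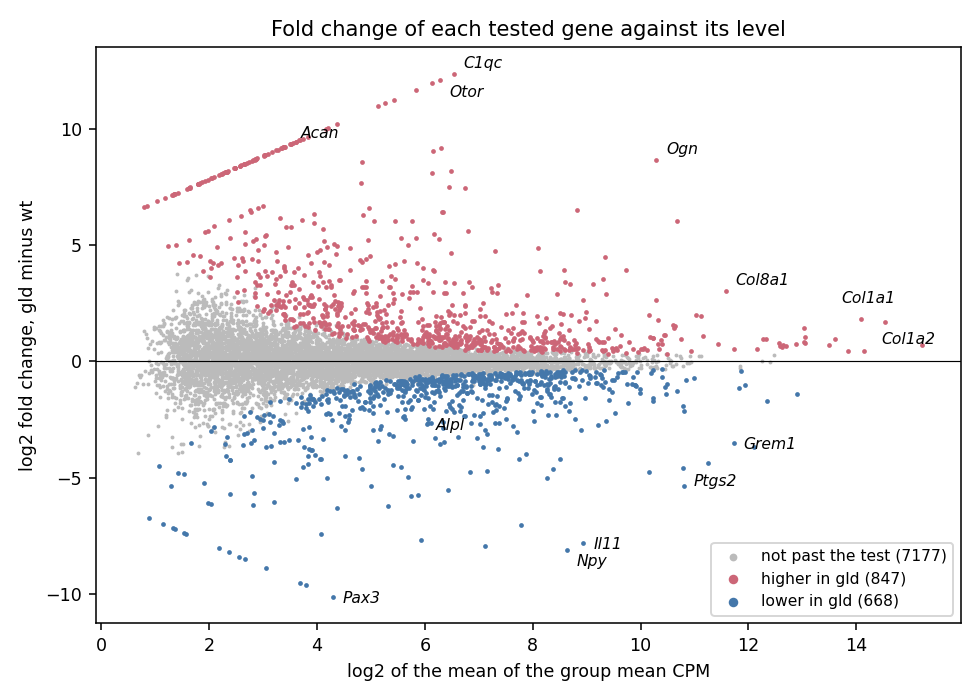
Log2 fold change, gld minus wt, of each of the 8692 tested genes (points) against the log2 of the mean of the group mean CPM. The 847 genes called higher in gld are red and the 668 called lower are blue, and the straight lines of points at the upper and lower edge are genes with no count in a group, whose fitted fold change depends on the prior count.

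The 10 largest increases in gld were ranked by fitted fold change, which for genes at 0 in a group depends on the prior count, and all 10 had no count in any wt library. Their bounds give no order against genes with counts in wt, so their place among the largest is not settled. They include the macrophage and leukocyte genes C1qc (complement), Rac2 (a leukocyte GTPase), Fcrls, Marco (a scavenger receptor) and Hcls1, at least 530-fold, 326-fold, 245-fold, 218-fold and 200.4-fold higher in gld. Otor, a small secreted protein of cartilage and the inner ear, was at least 441-fold higher, Npvf, a neuropeptide precursor, at least 118-fold, Scrg1 at least 104-fold, the bone proteoglycan gene Omd at least 102-fold and Shisa2 at least 81.0-fold. The largest edgeR adjusted p among these 10 was 1.77e-05, for Shisa2. Among the 10 largest decreases, Pax3, a transcription factor of neural crest and muscle precursors, had 70, 167 and 106 counts in wt and 0 in each gld library, and was at least 166.5-fold lower in gld. The cytokine gene Il11 fell by 7.81 ± 0.34 (SE) on the log2 scale, and fell by 8.62 without gld 2. The neuropeptide gene Npy had 1738, 2470 and 2577 counts in wt and 2, 1 and 34 in gld, and Rab3c had 856, 1735 and 1178 in wt and 1, 13 and 29 in gld. Several genes had gld counts in 1 library alone, so that library sets their fold and their place among the largest decreases. These were the scavenger receptor gene Olr1 (494, 1029 and 887 counts in wt; 14 in gld 1), the stromelysin gene Mmp10 (219, 468 and 373; 7 in gld 1), Krt23 (190, 231 and 243; 13 in gld 1) and the T cell receptor gene Trbc2 (85, 76 and 188; 6 in gld 2). The transcription factor gene Gata3 had 239, 317 and 338 counts in wt and 13, 10 and 0 in gld. The largest edgeR adjusted p of these genes was 4.84e-05, for Trbc2, and their calls held without each library in turn. Ptger2, a receptor for prostaglandin E, had 93, 91 and 90 counts in wt and 0, 1 and 1 in gld, and its pooled level was 203-fold higher in wt (95% counting interval 55.7 to 1686).

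Collagen transcripts rose as a group in gld. Of 21 tested collagen genes of 29, 15 rose, 1 fell and 5 did not pass, and adjusted over the list alone 17 rose and 1 fell. Col8a1 and Col8a2, the chains of the short-chain collagen VIII, rose by 3.02 ± 0.10 and 3.93 ± 0.15 on the log2 scale, Col11a1, a minor fibrillar collagen, rose by 3.38 ± 0.22, and Col1a1 rose by 1.83 ± 0.12 (SE, edgeR adjusted p from 5.56e-11 to 9.11e-08). The list's median was 1.68, with a camera adjusted p = 2.10e-08 and an adjusted p = 0.237 with an estimated correlation. Col1a1 and Col1a2 together took 1.98% ± 0.38 of all counts in wt and 5.96% ± 0.32 in gld (SD, n = 3). In the same libraries the summed level of macrophage and osteoclast markers was 495.5 ± 104 CPM in wt and 4520 ± 2020 CPM in gld (SD, n = 3).

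Proteoglycan genes rose too: of 20 tested of 31, 10 rose and 10 did not pass, and adjusted over the list alone 10 rose. Ogn rose by 8.65 ± 0.27 (9.30 without wt 2), lumican (Lum), which regulates collagen fibrils, by 2.01 ± 0.11 and Prelp by 1.5 ± 0.16 on the log2 scale, beside Omd (largest edgeR adjusted p = 9.93e-06). The median was 1.46, with a camera adjusted p = 2.88e-06 and an adjusted p = 0.0800 with an estimated correlation. Matrix glycoproteins went both ways: of 35 tested of 54, 13 rose, 6 fell and 16 did not pass, and adjusted over the list alone 14 rose and 6 fell. Ccn3 rose by 3.89 ± 0.16, the fibrillin gene Fbn2 by 3.31 ± 0.14 and the microfibril gene Mfap2 by 1.96 ± 0.14, and thrombospondin (Thbs1) fell by 2.12 ± 0.13 on the log2 scale (largest edgeR adjusted p = 1.7e-07). The glycoprotein list's median was 0.37, with a camera adjusted p = 0.0423 and an adjusted p = 0.41 with an estimated correlation. That call was lost without wt 1 (adjusted p = 0.0569), wt 2 (0.0908), wt 3 (0.0963) or gld 2 (0.0631).

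Genes that cleave, process or bind the matrix changed in both directions, and camera called none of their lists, while fry called the proteases (adjusted p = 0.0446) and the collagen processing genes (adjusted p = 0.0346). Of 29 tested matrix proteases and inhibitors of 46, 9 rose and 8 fell, as also when adjusted over the list alone (camera adjusted p = 0.912). The serine protease gene Htra3 rose by 3.26 ± 0.16 and cathepsin K (Ctsk), a collagen-degrading protease, by 1.43 ± 0.13, and Adam12 fell by 2.66 ± 0.24 on the log2 scale, beside Mmp10 (largest edgeR adjusted p = 1.69e-06). Of 14 tested collagen processing and crosslinking genes of 24, 5 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.552). The crosslinking enzyme genes Loxl1 and Loxl2 fell by 1.02 ± 0.10 and 1.17 ± 0.13, and P4hb rose by 0.93 ± 0.20 (largest edgeR adjusted p = 0.00481), and Plod2 had 1 count in wt, a pooled ratio of 109.9 (95% counting interval 19.5 to 4369). Of 14 tested integrin and adhesion genes of 21, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.86). Itgb3 fell by 3.13 ± 0.37 and Itga1 and Itga6 rose by 0.87 ± 0.14 and 2.13 ± 0.48 on the log2 scale (largest edgeR adjusted p = 0.00551).

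**Figure D3:**
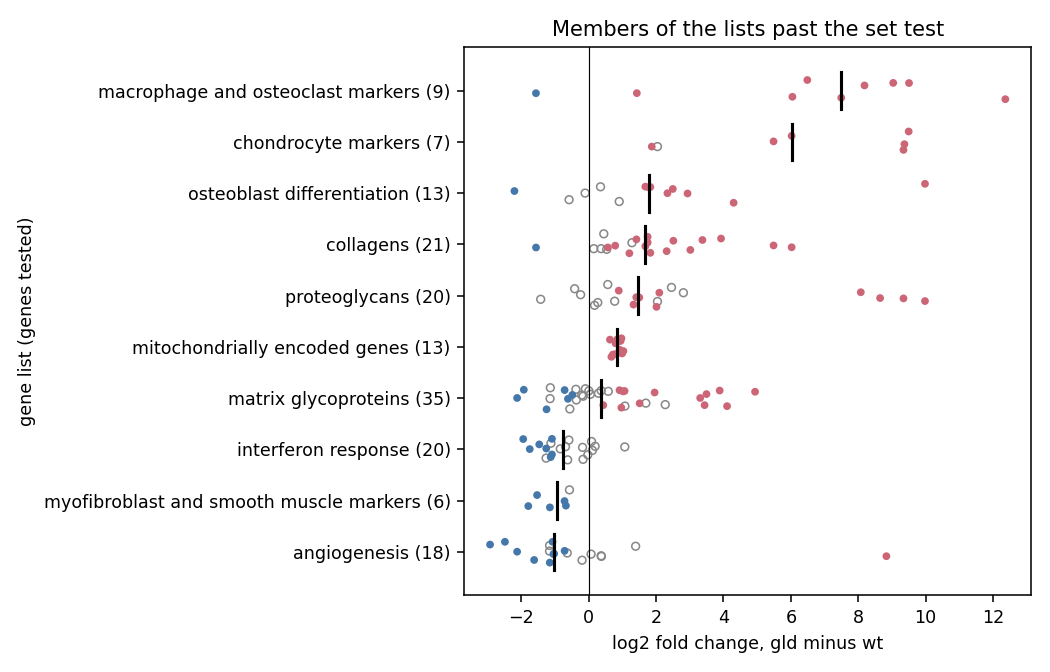
Log2 fold change, gld minus wt, of the tested members (points, spread vertically for legibility) of the 10 lists past the camera test, with the number of tested genes in brackets and a black bar at each list's median. Filled red and blue points passed the edgeR test, open points did not; medians of fitted values run from −1.03 for angiogenesis to 7.5 for macrophage and osteoclast markers.

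Most of the tested osteoblast and chondrocyte markers rose in gld, but these lists overlap with those above. Col1a1, Col1a2, Col9a2 and Col11a2 are also in the collagen list, and Omd and Acan in the proteoglycan list. The osteoblast genes Bglap, Spp1 and Sp7, looked up after the counts were seen, had 1, 4 and 20 counts over the 6 libraries, too few to compare. Of 13 tested osteoblast differentiation genes of 27, 8 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell. Col1a2 and the cadherin gene Cdh11 rose by 1.68 ± 0.12 and 1.79 ± 0.13, and Alpl, the alkaline phosphatase of mineralizing cells, fell by 2.20 ± 0.18 on the log2 scale, from 222 ± 40.5 to 48.2 ± 5.53 CPM (largest edgeR adjusted p = 7.97e-07). The list's median was 1.79, with a camera adjusted p = 0.00124 and an adjusted p = 0.237 with an estimated correlation. The transcription factor gene Runx2, named after its value was seen, had 0.35 ± 0.77 (edgeR adjusted p = 0.843), on 7, 12 and 23 counts in wt and 11, 33 and 33 in gld. Chondrocyte markers rose, 6 of 7 tested of 17, also adjusted over the list alone, with a median of 6.02. With genes at 0 in a group at their bound, that median was 5.13 without wt 2 and 5.35 without wt 3, and as fitted 7.46 without wt 1, 6.83 without wt 2, 6.82 without wt 3 and 6.81 without gld 3, where 8 genes were tested. Sox9, the transcription factor of cartilage formation, rose by 1.87 ± 0.11, the collagen genes Col11a2 and Col9a2 by 6.02 ± 0.43 and 5.49 ± 0.42 (Col9a2 by 4.90 without wt 2), and aggrecan (Acan), without a count in wt, was at least 65.3-fold higher (largest edgeR adjusted p = 2.01e-05). The camera adjusted p was 3.11e-07, and the adjusted p = 0.0800 with an estimated correlation.

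Osteocyte markers gave 2 that rose and 1 that fell of 5 tested of 12, also adjusted over the list alone (camera adjusted p = 0.787, direction up, with a mean of 2.12 and a median of −0.25). Podoplanin (Pdpn) fell by 0.65 ± 0.10 on the log2 scale (edgeR adjusted p = 0.00038), and Phex, without a count in wt, was at least 20.6-fold higher (edgeR adjusted p = 0.00349). The matrix protein gene Dmp1 had 2 counts in wt, both in wt 1, and a pooled ratio of 23.95 (95% counting interval 6.39 to 202), with an edgeR adjusted p = 0.0392. That call was lost in limma-voom, without the low-count filter, with the replicate block, and without wt 2 (0.134), wt 3 (0.157), gld 1 (0.126), gld 2 (0.154) or gld 3 (0.0952). Of 8 tested tendon and suture fibroblast markers of 17, 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.552), among them the tendon gene Tnmd, which rose by 3.94 ± 0.34, Fmod, by 1.33 ± 0.15, and Msx1, by 2.40 ± 0.38 on the log2 scale (largest edgeR adjusted p = 0.000398). Myofibroblast and smooth muscle markers fell: 5 of 6 tested of 12, also adjusted over the list alone, with a median of −0.93, a camera adjusted p = 0.000228 and an adjusted p = 0.107 with an estimated correlation. Smooth muscle actin (Acta2) fell by 1.15 ± 0.08, Tagln by 1.79 ± 0.14, Cnn1 by 1.53 ± 0.17 and Myl9 by 0.67 ± 0.105 on the log2 scale (largest edgeR adjusted p = 0.000311).

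Macrophage and osteoclast markers were far higher in gld. Of 9 tested of 24, 8 rose and 1, the lipopolysaccharide co-receptor gene Cd14 (named after its value was seen), fell by 1.56 ± 0.24 on the log2 scale, also adjusted over the list alone. The complement genes C1qb, C1qc and C1qa and the lysosomal gene Laptm5 had 0 to 8 counts in each wt library and 334 to 1441 in each gld library (largest edgeR adjusted p = 1.02e-06), and C1qa was not past in limma-voom (adjusted p = 0.0699). The list's summed level was 446, 615 and 425 CPM in wt and 2744, 4099 and 6717 CPM in gld. Its median was 7.5, or 6.49 with genes at 0 in wt set to their bound, with a camera adjusted p = 4.55e-06 and an adjusted p = 0.278 with an estimated correlation. The fitted median was 6.63 without wt 1, 8.81 without wt 2 and 6.90 without gld 3, and at the bounds it was 5.58 without wt 3 and 5.71 without gld 3. These markers moved with the collagen, proteoglycan, osteoblast and chondrocyte lists, being higher in the same 3 libraries, and of the 9 Ctsk is also in the protease list. Most markers of other cell types had too few counts to be tested, which does not show that such cells were absent. The macrophage genes Csf1r, Tyrobp and Fcer1g were also listed at 0, while other macrophage markers rose. Lpl, the 1 tested adipocyte marker of 12, fell by 2.32 ± 0.17 (camera adjusted p = 0.0613), and Acta1, the 1 tested skeletal muscle marker of 16, rose by 2.59 ± 0.54 (camera adjusted p = 0.142), each also adjusted over the list alone. Neither of the 2 tested endothelial markers of 12 passed, also adjusted over the list alone (camera adjusted p = 0.449), with Plvap at 2.43 ± 1.25 and Kdr at 1.51 ± 1.16. Over the alternatives that tested them, Plvap ran from 1.84 to 4.75 and Kdr from 0.93 to 4.57. Of 6 tested glial and neural markers of 11, 1 rose and 1 fell (camera adjusted p = 0.912), and of 2 tested epithelial markers of 9, Cdh1, without a count in wt, was at least 42.2-fold higher (camera adjusted p = 0.552), also adjusted over the list alone. Neither of 2 tested sex-linked transcripts of 6 passed, also adjusted over the list alone (camera adjusted p = 0.69), with Xist at 0.01 ± 0.23 and Kdm5d at 2.14 ± 1.18. Kdm5d rests on 0, 1 and 10 counts in wt and 11, 31 and 25 in gld, and ran from 1.64 to 4.65 over the alternatives.

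**Figure D4:**
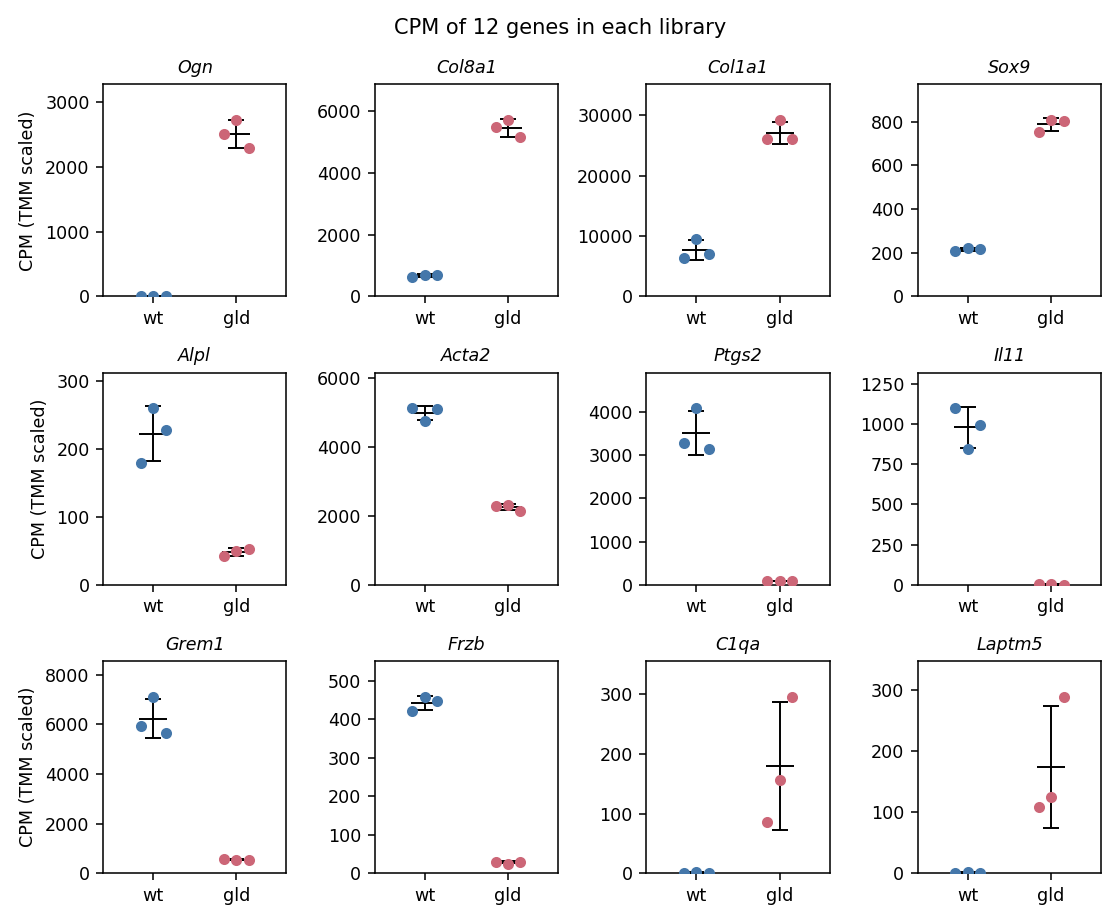
CPM on the TMM scale of 12 genes in each wt (blue) and gld (red) library, with the mean (bar) and SD of 3 libraries per group, each axis starting at 0. Col1a1 goes from 7621 to 27140 CPM and Ptgs2 from 3501 to 85.2 CPM, and the SD in gld is 107 CPM for C1qa around a mean of 180 CPM.

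Inflammatory genes changed in both directions in gld, and camera called the interferon response and angiogenesis lists lower. Of 20 tested inflammatory and NF-kB genes of 32, 7 rose and 6 fell, and adjusted over the list alone 9 rose and 8 fell (camera adjusted p = 0.912, direction down, with a median of 0.16 and a mean of 0.002). Ptgs2 fell by 5.36 ± 0.13 and Ptges, the prostaglandin E synthase gene, by 2.76 ± 0.17, and the complement gene C3 rose by 2.86 ± 0.15 on the log2 scale (largest edgeR adjusted p = 3.24e-08). Of 20 tested interferon response genes of 34, 7 fell, none rose and 13 did not pass, and adjusted over the list alone 9 fell. The interferon-induced genes Ifi27l2a, Usp18 and Ifi44 fell by 1.94 ± 0.28, 1.46 ± 0.22 and 1.26 ± 0.21, and the signal transducer gene Stat2 fell by 1.09 ± 0.23 (largest edgeR adjusted p = 0.0033). The interferon list's median was −0.76, with a camera adjusted p = 0.00159 and an adjusted p = 0.577 with an estimated correlation, and it is the 1 list called by camera that fry did not call (adjusted p = 0.052). Angiogenesis genes also fell, 9 of 18 tested of 24, with 1 that rose, and adjusted over the list alone 11 fell and 3 rose. The growth factor gene Vegfd fell by 2.48 ± 0.17, Angptl2 by 1.62 ± 0.15 and the receptor gene Nrp1 by 1.07 ± 0.13, beside Thbs1, an inhibitor of vessel growth (largest edgeR adjusted p = 2.46e-05). The angiogenesis list's median was −1.03, with a camera adjusted p = 0.00238 and an adjusted p = 0.287 with an estimated correlation.

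Secreted modulators of Wnt and BMP signals changed strongly in both directions. Of 17 tested Wnt pathway genes of 29, 6 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.786). The Wnt antagonist genes Frzb, Sfrp1 and Dkk2 fell by 3.96 ± 0.15, 1.42 ± 0.09 and 2.77 ± 0.30, and Sfrp2, of the same antagonist family, rose by 2.04 ± 0.14 on the log2 scale (largest edgeR adjusted p = 1.06e-05). Of 22 tested TGF-beta and BMP pathway genes of 29, 8 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.946, direction up, with a median of 0.14 and a mean of −0.23). The BMP antagonist gene Grem1 fell by 3.52 ± 0.11 and the activin gene Inhba fell by 2.94 ± 0.13, while Tgfb2 rose by 2.37 ± 0.18 (largest edgeR adjusted p = 3.55e-07). Of 7 tested genes by which osteoblasts regulate osteoclasts, of 11, 1 rose and 2 fell, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.912). Efnb2 rose by 1.05 ± 0.22 (edgeR adjusted p = 0.00333). Tnfsf11, the gene of RANK ligand, was at −0.64 ± 0.20 with an edgeR adjusted p = 0.0396, a call lost without wt 2 (0.173), wt 3 (0.0838), gld 1 (0.0787) or gld 2 (0.137) and with the replicate block.

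Of 23 tested Fas pathway and apoptosis genes of 37, 2 rose, 2 fell and 19 did not pass, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.912). The death receptor gene Tnfrsf10b fell by 1.10 ± 0.17 on the log2 scale (edgeR adjusted p = 0.000313). Cflar, the gene of the caspase inhibitor c-FLIP, fell by 0.64 ± 0.16 (edgeR adjusted p = 0.0115), a call lost without wt 2 (0.0553). Dap rose by 0.47 ± 0.12, a call lost without gld 1 (0.0749) or gld 3 (0.0516), and the survival gene Mcl1 rose by 0.49 ± 0.13, a call lost without wt 1 (0.0741), wt 3 (0.0628) or gld 3 (0.0723), and both were lost when scaled by library size alone.

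Mitochondrially encoded genes all rose, 13 of 13, also adjusted over the list alone, with a median of 0.84, a camera adjusted p = 7.06e-07 and an adjusted p = 0.107 with an estimated correlation. The cytochrome oxidase genes mt-Co2 and mt-Co1 rose by 0.97 ± 0.09 and 0.95 ± 0.10, and the complex I genes mt-Nd1 and mt-Nd4 by 0.80 ± 0.075 and 0.96 ± 0.09 on the log2 scale (largest edgeR adjusted p = 6.1e-06). Mitochondrial genes took 9.2% ± 0.45 of the counts in wt and 13.8% ± 0.49 in gld (SD, n = 3). Their counts are uncertain, because nuclear copies held about the same numbers: mt-Co3 had 139910 counts in sum and the pseudogene Gm28437 146390.

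The remaining lists had no camera call. Of 9 tested autophagy genes of 18, 2 rose and 2 fell, and adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.912, direction down, with a median of −0.07 and a mean of 0.08), and Gabarapl1 fell by 1.75 ± 0.14 while Lamp2 rose by 0.52 ± 0.11. Of 13 tested proliferation genes of 24, 1 rose, also adjusted over the list alone, and of 12 tested unfolded protein response genes of 18, 1 rose and none adjusted over the list alone (camera adjusted p = 0.69 each). Of 10 tested hypoxia and glycolysis genes of 17, 1 rose and 2 fell, and adjusted over the list alone 1 rose and 3 fell (camera adjusted p = 0.912, direction down, with a median of 0.02 and a mean of −0.29). Ndrg1 rose by 2.97 ± 0.21 and Adm fell by 1.73 ± 0.21. Of 7 tested immediate early genes of 15, 2 rose and 1 fell, and adjusted over the list alone 2 rose and 2 fell (camera adjusted p = 0.69), and Egr1 and Klf4 rose by 1.41 ± 0.14 and 1.36 ± 0.16. Camera called 10 of the 31 lists, 7 up and 3 down. With an estimated correlation 0 lists passed after adjustment and 6 had an unadjusted p under 0.05, and fry called 19.

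The gld strain is a congenic that carries DNA of the donor strain around Fasl, so genes near Fasl could differ through that DNA as well. Within 20 Mb of Fasl (GRCm38 chromosome 1, 141780689 to 181788495) 28 of 140 tested genes (20%) were called, against 1479 of 8400 (17.6%) elsewhere, an odds ratio of 1.17 (95% confidence interval 0.741 to 1.79) with p = 0.436 in Fisher's exact test, two-sided. The median absolute log2 fold change was 0.51 inside and 0.47 outside the window.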

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

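The fits on thinned libraries, without mitochondrial genes and pseudogenes, and on genes with a single-transcript end were chosen after the data were seen. Under the alternatives to the fit and filter, edgeR, DESeq2 or limma-voom called from 1224 to 1722 genes against 1515, and none of the 1515 genes that an alternative tested changed sign. Scaling by library size alone called 1695 and shared 1388 of them, DESeq2 called 1722 genes and shared 1478, limma-voom called 1471 and shared 1366, thinning gave 1525 and shared 1391, and single-transcript ends alone gave 1325 and shared 1290. Leaving out each library gave from 1224 (without wt 3) to 1424 calls. Genes lower in gld numbered 431 at an adjusted p of 0.01 and 416 with at least a 2-fold change, against 668, because fewer genes meet a stricter threshold. Replicates share numbers across groups, but same-numbered libraries' deviations correlated at −0.0231, −0.015 and −0.0227 and in these deviations no library correlated best with its own number. No pairing by number was therefore seen, though so few libraries cannot rule out a shared isolation or batch. With the replicate number as a block edgeR called 1359 genes, 1335 shared, and of the lists only matrix glycoproteins lost its call (camera adjusted p = 0.0999). With an estimated correlation, camera called 0 lists against 10, with 6 under an unadjusted p of 0.05. That setting also missed the self-test's planted list. Because the self-test drew its genes independently, it cannot decide between these settings for lists of correlated genes. Without mitochondrial genes and pseudogenes, or on single-transcript ends, matrix glycoproteins also lost its call (0.0877 and 0.426). Of 109 called named genes, 94 kept their call under every alternative that tested them, and 15 lost it in at least 1. Named genes with a shared end, such as Pax3, were not tested in the fit on single-transcript ends. Fas stayed between −0.25 and 0.11 (lowest edgeR or other adjusted p = 0.749). Within 10, 20 or 40 Mb of Fasl the odds ratio stayed between 1.17 and 1.29 (Fisher's exact p from 0.0958 to 0.436). Over the whole of chromosome 1 the odds ratio was 1.23 (Fisher's exact p = 0.0597). Alternatives written for normalized values or an authors' test table had nothing to apply to in raw counts. Depth sets which genes can be tested: 7252 after thinning against 8692.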

Other observations

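Tests chosen after their results were seen were those of the positional transcription factor families, of T cell, NK cell and mast cell genes, of copies elsewhere in the genome and of the splits for the gene count. Transcription factors that mark position in the head and trunk differed in both directions. Of 37 tested members of such families (Hox, Pax, Tbx, Dlx, Msx, Foxc, Foxd and others, but no other Fox genes), 10 rose and 7 fell in gld. Barx1, of the jaw and stomach mesenchyme, rose by 4.75 ± 0.23 (SE) on the log2 scale, the skull regulator Foxc1 rose by 1.64 ± 0.13, Foxd1 had 13, 1 and 1 counts in wt and 681, 667 and 613 in gld, and Hoxa2, a gene of the second pharyngeal arch, had no count in wt and was at least 75.9-fold higher in gld (largest edgeR adjusted p = 1.34e-05). Tbx18 fell by 3.13 ± 0.18, En1 by 3.27 ± 0.31 and Twist2 by 2.34 ± 0.18 (largest edgeR adjusted p = 2.95e-06), beside Pax3.

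The T cell, NK cell and mast cell genes that could be tested, 4 of 30, fell in gld. The T cell receptor genes Trbc2 and Trdc had 85, 76 and 188 and 17, 35 and 39 counts in wt, and 0, 6 and 0 and 0, 0 and 0 in gld, and Gimap9 had 20, 58 and 41 in wt and 0, 5 and 0 in gld (largest edgeR adjusted p = 0.00476). The basophil and mast cell gene Mcpt8 had 1 count in gld and a pooled count 102-fold higher in wt (95% counting interval 17.8 to 4098), a call in edgeR (adjusted p = 0.00344) that was lost without wt 3 (0.062). Ighm, the 1 tested B cell gene of 7, had 1 count in wt and 13, 21 and 31 in gld (edgeR adjusted p = 0.022), a call lost without wt 2 (0.103), wt 3 (0.124) or gld 1 (0.056), in limma-voom, without the low-count filter and with the replicate block. Apart from Trbc2 and Pax3, the genes named here were chosen after their values were seen.

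Many genes that nearly every cell uses have no or few counts. Low sequencing depth would empty the families evenly, but proteasome and respiratory chain genes with a single-transcript 3′ end held a median of 770 counts. Reads shared with pseudogenes or paralogs elsewhere in the genome would leave genes without copies full, but 25 such genes with a shared end that matches no transcript of another gene (90% identity over 50 bases) also had a median of 0, against 1579 for 27 with a single-transcript end. Of ribosomal protein genes without copies, 4 with a shared end had a median of 3 and 9 with a single-transcript end 76. Their two-sided permutation p was 0.101, so copies were not set aside for that family. A candidate explanation is that reads lying in exons of more than 1 annotated transcript were not counted: the median of the 47 proteasome and respiratory chain genes with a shared end was 0. The annotation the counter used stays open, and Csf1r, with a single-transcript end and 0 counts, goes against a simple rule. So do the respiratory chain genes Uqcrc2 and Uqcrq, also at 0 with single-transcript ends. Of the 46 proteasome and respiratory chain genes with a single-transcript end, 12 (26.1%) had under 30 counts, against 42 of 47 (89.4%) with a shared end.

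Macrophage and osteoclast marker genes were higher in gld. Lower sequencing depth of the wt libraries would lose the difference on thinning, but the median log2 fold change of the 8 markers still tested was 6.81, also with genes at 0 in wt set to their bound. Leukocytes of every kind being more abundant in gld would raise T cell, NK cell and mast cell genes, but the 4 tested of 30 had a median of −6.19, or −5.77 with Trdc at its bound, and was as fitted −8.38 without gld 2 and −6.78 without gld 1, and at the bounds −4.72 without gld 1 and −5.18 without gld 3. RNA from macrophages in the gld cultures may account for it, as a second panel of macrophage genes had a median of 4.68 over its 5 tested members of 24 (as fitted 7.58 without wt 2, 5.98 without gld 1, 5.64 without wt 3 and 5.27 without wt 1, and 3.98 without wt 2 and 3.95 without wt 3 with genes at 0 at their bound), with Cd53 the 1 that fell. Lyz2 belongs to the first list, so it is part of the pattern and no separate evidence. It reached 3236 ± 1621 CPM in gld, of a summed 4520 ± 2020 CPM for that list (SD, n = 3). Osteoblasts and fibroblasts also express Ctsk, and whether the genotype or the isolation brought more macrophages was not tested.

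Positional transcription factor genes differ in both directions. Lower sequencing depth of the wt libraries would lose the difference on thinning, but 17 of the 33 members still tested (51.5%) were called, all of them called in the full libraries too, against a median of 21.2% and a 95th percentile of 33.3% in random sets. Cells of a different place or kind at isolation would raise the share of called members, which was 45.95% against a median of 16.2% and a 95th percentile of 27.0% in 10000 random sets matched on expression. The families were chosen after the data were seen, so the random sets do not measure how unusual that share is. An effect of Fasl on these genes could give that share too, and because cells of each genotype come from their own mice the 2 cannot be told apart here. Of the members that fell, Prrx1 lies within 20 Mb of Fasl, where donor DNA could matter as well. Pax3, Twist2 and En1 lie on the same chromosome outside that window.

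In edgeR, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 1515 genes, and the highest other gave 0. For the lists, camera gave 10 in the real split, 1 of the 10 splits, and at most 3 in the others. With 10 splits the share cannot fall under 0.05, so the splits are too few.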
